A study of Mus musculus with 24 samples.

How the data were processed

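Per the labels, γδ T cells were sorted as PLZF+ or PLZF- from adipose tissue, spleen, lung and lymph node of PLZF-GFP mice and 24 Smart-seq2 libraries were made, 3 for each of 8 groups. Libraries were treated as separate samples, though the series text speaks of 2 replicates for each subset. Reads were handled with HISAT 0.1.6, SAMtools 1.2 and Cufflinks 1.2 on mm10, per the submitters' processing notes. The deposited table holds log2 values for 7926 genes in 24 libraries with a p-value and a q-value per gene, and its header, per the file headers, lists TMM factors (0.705681 to 1.35757), a variable for tissue and the program Qlucore. A second file repeats the first 25 genes and was not used. The authors tested 42591 genes and kept those with q under 0.05.

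Which test the authors' p-values came from was checked by repeating it. A one-way test over the 4 tissues, PLZF ignored, returned the authors' p-value for 7915 genes (99.86%, within 0.001 on the log10 scale), a test over the 8 groups did so for 15 genes and a test over the 2 subsets for 0. The 11 genes that differed are entries merged from several, and they were excluded from the tests. The table is thus limited to genes that passed a tissue test on this scale, whether or not they differ. On recovered reads, 3192 of 7913 genes (40.3%) stay within the largest p-value the authors kept (0.0093).

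The deposited log2 values were found to equal log2 of reads plus 0.5, plus 1 term per library and 1 per gene, so whole reads could be worked back for 7924 genes (99.97%). Gene terms were unrelated to exon length (Spearman -0.007 over 5447 genes). A zero therefore sits at a floor that depends on depth, and relative depth in lung libraries 2 and 3 was 0.170 and 0.177 (PLZF-) and 0.312 and 0.329 (PLZF+). Reads per library were 202928 to 802109 in adipose tissue, 289751 to 533620 in lymph node and 370204 to 808465 in spleen, counted over the genes of the table only. Between 25.4% and 61.9% of genes had 0 reads in a library, 2435 genes (30.7%) were read in at most 3 libraries and 1782 in all 24. All 24 pairs of replicates differed by more than sampling noise (chi-square per gene 4.2 to 158.4, correlation 0.831 to 0.976), so none are copies of the same library.

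Tests, gene lists and the rule for named genes were chosen before the data were examined. That choice foresaw normalized values and took log2 of value plus 1; since the table holds log2 values they were used as they are, with the filter of a value of at least 1 in at least 3 libraries (5858 genes). Group means of the 8 groups were fitted with limma 3.58.1 (R 4.3.3) with a shared spread and a trend, no replicate block, and Benjamini-Hochberg adjusted p under 0.05 as threshold. PLZF+ was compared with PLZF- averaged over tissues and in each tissue, adipose tissue and lung with the mean of spleen and lymph node within each subset, and the differences between the 4 PLZF contrasts by an F test on 3 degrees of freedom. Lists (24 with at least 3 tested members, 216 tests in 9 comparisons) were tested by camera with the preset correlation of 0.01 and with an estimated one, and by fry. Recovered reads were tested as log2 of normalized reads plus 1 for 2846 genes with a mean of at least 10, and by limma voom; both were chosen after the values were seen. Normalized reads quoted for a gene are recovered reads scaled for depth, as mean ± SD over libraries. Folds against groups without reads are given as "at least", with a floor of 3 reads per library. Other tools were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

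Genes named are those of a panel of 21 in the PLZF comparisons, and by rule the 8 largest increases and decreases past the test over all tissues, with a mean in the higher subset above the median of tested genes and the same side in all 4 tissues. In single tissues they are the 3 largest each way, and between tissues the 8 largest each way, with every library of 1 group above every library of the other. The rule adds the 8 smallest adjusted p of the interaction and the 4 members of each list with the smallest adjusted p; gene models without a name are left out, and a few genes the rule names are not reported here.

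Whether equal replicate numbers pair PLZF+ and PLZF- libraries was checked from the correlation of their deviations from group means. It was 0.630, 0.147 and 0.544 in adipose tissue, 0.341, 0.189 and 0.197 in lymph node and 0.511, 0.349 and 0.218 in lung, so numbers were taken to pair the samples there. This is weaker for adipose library 2, where another number gave 0.273 (0.404 against 0.365 for its own on recovered reads), and for lung library 3 (0.039 on recovered reads); in spleen it was -0.019, -0.059 and -0.050, and they share a number only. No label states the pairing. Alternatives were 2 other pseudocounts, 2 other filters, 2 other scalings, library weights, fits on the groups compared only, replicate blocks and each library left out in turn, and, chosen after the values were seen, recovered reads (with their own genes or those of the deposited values), voom, deposited values on the genes of the recovered reads, and fits without adipose or lung libraries 2 and 3.

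The methods were tested on simulated data with known folds in 50 genes per size. At an absolute log2 fold of 1 the deposited scale recovered 56%, recovered reads 72% and voom 84%, and all 3 recovered 100% from log2 2 upward, with 4, 3 and 8 unchanged genes called. The simulation used 1 dispersion (0.128), while a random split of the real libraries called 235 genes, so false calls may be more frequent in them. Without any tissue difference, the deposited scale still called 1685 of 6499 genes (25.93%) between PLZF- lung and the lymphoid tissues, 1651 of them higher, and 0 in the other 3 tissue comparisons, while recovered reads called at most 2 and voom 0. The simulated one-way test over tissues passed the authors' limit for 926 of 7494 genes on the deposited scale and 95 on recovered reads, all without a difference. Working back reads gave whole numbers for 99.89% of 7913 simulated genes.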

Results

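RNA was sequenced from γδ T cells that did (PLZF+) or did not (PLZF-) carry the GFP reporter of PLZF, a transcription factor of innate-like lymphocytes. Cells came from epididymal adipose tissue, lung, spleen and inguinal lymph node of male C57Bl/6 mice and were made into libraries with Smart-seq2, 8 groups of 3 libraries and 24 in all. The series describes 2 replicates per subset with 10 mice pooled in each, while 3 libraries per group are labelled, and nothing tells whether the 3 hold separate pools. The p-values therefore measure the spread between these libraries. Genes in the table are those the authors kept for a difference between tissues at q under 0.05, 7926 of 42591, so PLZF genes alike in all 4 tissues were not analysed here and the comparisons of tissues start from genes picked by a test for such a difference. Counts of list members are out of those kept by that test and tested here, not out of the whole list. Between tissues the share of members past the test may be raised by that choice.

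Whole reads were recovered for 7924 genes, and libraries held between 57903 and 876360 of them. Lung replicates 2 and 3 were shallow in both subsets, with 64786 and 57903 reads in PLZF- and 114565 and 121433 in PLZF+ libraries, against 555031 and 876360 in replicate 1. Marker genes of other cells (76 genes) took 3.52%, 6.13% and 8.10% of reads in PLZF- adipose libraries 1 to 3 and 4.69%, 4.70% and 7.28% in PLZF+ ones. In lung they took 4.54%, 10.8% and 5.82% in PLZF- and 6.29%, 10.0% and 7.17% in PLZF+ libraries. Endothelial markers such as Cldn5 stood at 56.3 and 201 normalized reads in PLZF- and PLZF+ adipose library 1, but at 6897 and 14670 in PLZF- and 5199 and 9497 in PLZF+ libraries 2 and 3. The 4 CD3 genes, which make the signalling part of the T cell receptor, were lowest in PLZF- adipose library 3 (369 normalized reads) and highest in PLZF+ lymph node (up to 4210).

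**Figure D1:**
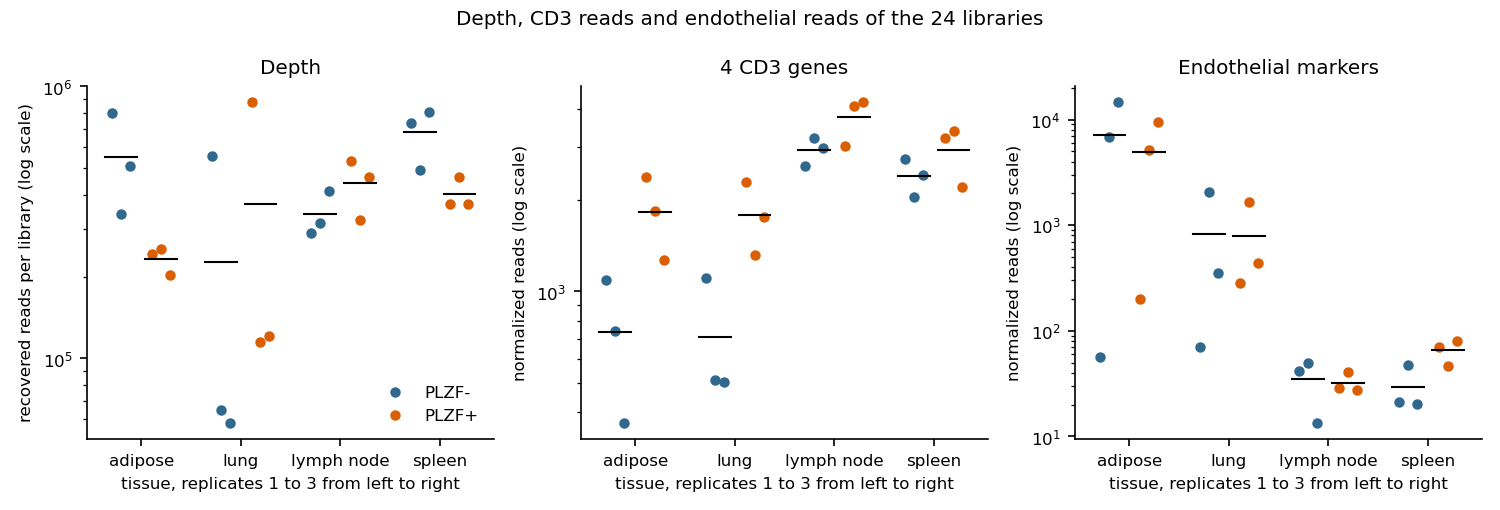
Recovered reads, summed normalized reads of 4 CD3 genes and of endothelial markers in each of the 24 libraries, by tissue and subset; bars are means of 3 libraries. Values are on log scales.

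Averaged over the 4 tissues, PLZF+ cells held more Il17a, which encodes the cytokine IL-17A, than PLZF- cells (log2 fold change 2.52 ± 0.55 SE, adjusted p = 0.0228, n = 12 v 12). They also held more Ccr6, the receptor for CCL20 (1.58 ± 0.31, adjusted p = 0.0132), more Ptgdr2, a receptor for prostaglandin D2 (2.74 ± 0.35, adjusted p = 0.00025), and more Ablim3, an actin-binding protein (3.49 ± 0.54, adjusted p = 0.00174). For Ablim3 the mean was 98.5 ± 112.5 normalized reads against 74.8 ± 172.1, with 293 and 553.6 in PLZF- adipose 2 and 3, and it did not pass by voom (adjusted p = 0.0548). Dapl1, a gene of resting lymphocytes, was lower in PLZF+ cells (-3.06 ± 0.39, adjusted p = 0.00025; 2.17 ± 3.12 against 34.0 ± 32.1 normalized reads, mean ± SD). So were Ccr9, the receptor for CCL25 (-2.13 ± 0.39, adjusted p = 0.00774; 45.5 ± 55.7 against 142 ± 123), and Sh2d1a, the adaptor SAP of SLAM-family receptors (-2.38 ± 0.38, adjusted p = 0.00174). Il17a was highest in PLZF+ lung, 333.7 ± 92.5 normalized reads against 13.2 ± 8.5 in PLZF- lung, while Ccr6 and Ptgdr2 were highest in PLZF+ lymph node (717.6 ± 109.6 and 363.6 ± 67.6). In all, 69 of 5858 tested genes passed, 37 higher and 32 lower (recovered reads: 51 higher and 39 lower of 2846, 62 shared in the same direction).

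Further genes higher in PLZF+ cells were Rbpms2, an RNA-binding protein (2.45 ± 0.43, adjusted p = 0.00521), Abhd15, a hydrolase-fold protein (1.57 ± 0.31, adjusted p = 0.0132), Prickle1, a planar cell polarity gene (1.89 ± 0.43, adjusted p = 0.0272), and Ramp3, a partner of the calcitonin receptor-like receptor (1.72 ± 0.37, adjusted p = 0.0214). Lower were Nsg2 (-2.67 ± 0.43, adjusted p = 0.00215), Gas7 (-1.88 ± 0.40, adjusted p = 0.0218), BE692007 (-1.89 ± 0.25, adjusted p = 0.00025), Cxcr5, the receptor for CXCL13 (-2.09 ± 0.51, adjusted p = 0.0479), and Ifit1bl1, an interferon-induced gene (-1.80 ± 0.44, adjusted p = 0.0485). Il17f (0.69 ± 0.64, adjusted p = 0.945), Il1rl1, the IL-33 receptor (0.28 ± 0.56, adjusted p = 0.973), and Areg, the growth factor amphiregulin (0.73 ± 0.49, adjusted p = 0.828), did not pass. The other 16 genes of the fixed panel, among them Zbtb16, Ifng, Tbx21 and Cd27, were not analysed here.

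Calls moved when 1 library was left out. Il17a passed no more without PLZF+ lymph node 2, PLZF+ spleen 1, PLZF+ spleen 2 or PLZF- lymph node 3 (adjusted p = 0.0501 to 0.0536), and Ramp3 passed no more without PLZF+ spleen 2 (adjusted p = 0.0522). Prickle1 was lost without any of PLZF+ adipose 1, PLZF+ lung 1, PLZF+ lymph node 2 and 3, PLZF+ spleen 2 and 3, PLZF- lung 1 and 3, PLZF- lymph node 1 and 2 and PLZF- spleen 1 (adjusted p = 0.0524 to 0.0623). For Cxcr5 each library except PLZF+ adipose 3, PLZF+ lymph node 1, the 3 PLZF+ lung libraries, PLZF- adipose 1 and PLZF- lung 1 did so (17 of 24, adjusted p = 0.0531 to 0.102), and for Ifit1bl1 each except PLZF+ adipose 1, PLZF+ lung 2 and PLZF- adipose 3 (21 of 24, 0.0509 to 0.107). With a replicate block Ifit1bl1 stood at 0.0514, or 0.0503 with the block within tissue. The count of 69 became 43 without PLZF- lymph node 3, 39 without PLZF+ lymph node 2, 43 without PLZF+ spleen 1 and 38 without PLZF+ spleen 2.

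Among the fixed lists, naive and lymphoid homing genes were lower in PLZF+ cells: 3 of 5 fell, 0 rose and 2 were not past the test (5 adjusted over the list alone). Its members Dapl1, Ccr9 and Foxp1, a regulator of lymphocyte quiescence (-0.90 ± 0.19, adjusted p = 0.0214; 199 ± 68 against 393 ± 174 normalized reads), passed, and Cd7 (-1.07 ± 0.33, adjusted p = 0.171) did not. For naive genes camera gave adjusted p = 6.39e-13 (0.0163 with an estimated correlation, and 0.141 so on recovered reads). No other list in any comparison passed with an estimated correlation (marked estimated from here on). Of 6 IL-17 programme genes, 2 rose, Ccr6 and Il17a, 0 fell and 4 were not past the test (2 over the list alone). For IL-17 genes camera gave adjusted p = 0.0290 (0.320 estimated). The IL-17 programme list passed no more without PLZF- adipose 3, PLZF- lymph node 1, PLZF- lung 2 or 3, PLZF- spleen 2, PLZF+ adipose 1, PLZF+ lymph node 3, PLZF+ lung 1 or PLZF+ spleen 2 (camera adjusted p = 0.0537 to 0.125). Among 9 tissue residency genes Ccr10, a chemokine receptor, rose (1.41 ± 0.32, adjusted p = 0.0277), 0 fell and 8 were not past the test, Itgae, the integrin that binds E-cadherin, among them (1.43 ± 0.36, adjusted p = 0.0557; 3 over the list alone). For residency genes camera gave adjusted p = 0.00232 (0.135 estimated). In the list of γδ T cell receptor genes 3 of 11 rose, 0 fell and 8 were not past the test (6 over the list alone). Those 3 are CD3 components, which αβ and γδ T cells share: Cd247 (0.98 ± 0.21, adjusted p = 0.0214), Cd3g (adjusted p = 0.0268) and Cd3e (0.96 ± 0.22, adjusted p = 0.0272). Tcrg-C2, a constant segment of the γ chain, did not pass (1.06 ± 0.27, adjusted p = 0.0557), and after quantile scaling 0 of the 11 did. For T cell receptor genes camera gave adjusted p = 1.31e-07 (0.135 estimated).

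Metabolic lists held few changes by PLZF. Hk2, a hexokinase, rose (1.06 ± 0.21, adjusted p = 0.0132; 45.9 against 19.8 normalized reads) as the only 1 of 5 glycolysis genes, with 0 that fell and 4 not past the test, such as Slc16a3, a lactate transporter (1.05 ± 0.33, adjusted p = 0.184; 3 over the list alone). For glycolysis genes camera gave adjusted p = 0.00394 (0.112 estimated). Of 14 lipid uptake and storage genes Dgat1, the last enzyme of triglyceride synthesis, rose (0.97 ± 0.24, adjusted p = 0.0485), 0 fell and 13 were not past the test (1 over the list alone). For lipid genes camera gave adjusted p = 0.699 (0.955 estimated). None of 13 nuclear genes of oxidative phosphorylation rose or fell (0 over the list alone), for instance Cox7c (-0.42 ± 0.21, adjusted p = 0.624) and Ndufs4 (0.31 ± 0.20, adjusted p = 0.786). For oxidative phosphorylation genes camera gave adjusted p = 0.699 (0.955 estimated). Of 4 fatty acid synthesis genes 0 rose and 0 fell (1 lower over the list alone). For these camera gave adjusted p = 0.0237 (0.280 estimated). It was 0.0650 to 0.0897 without PLZF- adipose 3, PLZF- lung 1, PLZF+ adipose 1 or PLZF+ lung 3. Among 5 αβ T cell markers Cd8b1, the CD8 beta chain, was lower (-3.38 ± 0.46, adjusted p = 0.000301), 0 rose and 4 were not past the test (1 over the list alone), and the median of this list changed sign with the scaling (-0.02 as deposited, 0.06 after quantile scaling). For αβ markers camera gave adjusted p = 0.0247 (0.0520 with a replicate block, 0.496 estimated). It was 0.0601 to 0.279 without PLZF- adipose 1, PLZF- lung 1, PLZF+ adipose 3 or PLZF+ lung 2. Immediate early genes, which follow activation and tissue handling, leaned down with 0 of 26 past the test (0 over the list alone; the median was -0.41 in adipose tissue and -0.58 in spleen but 0.60 in lung). Camera gave them adjusted p = 0.0112 (0.613 estimated). It was 0.0640 to 0.150 without PLZF- adipose 3, PLZF- lung 1, PLZF+ adipose 1 or PLZF+ spleen 3.

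**Figure D2:**
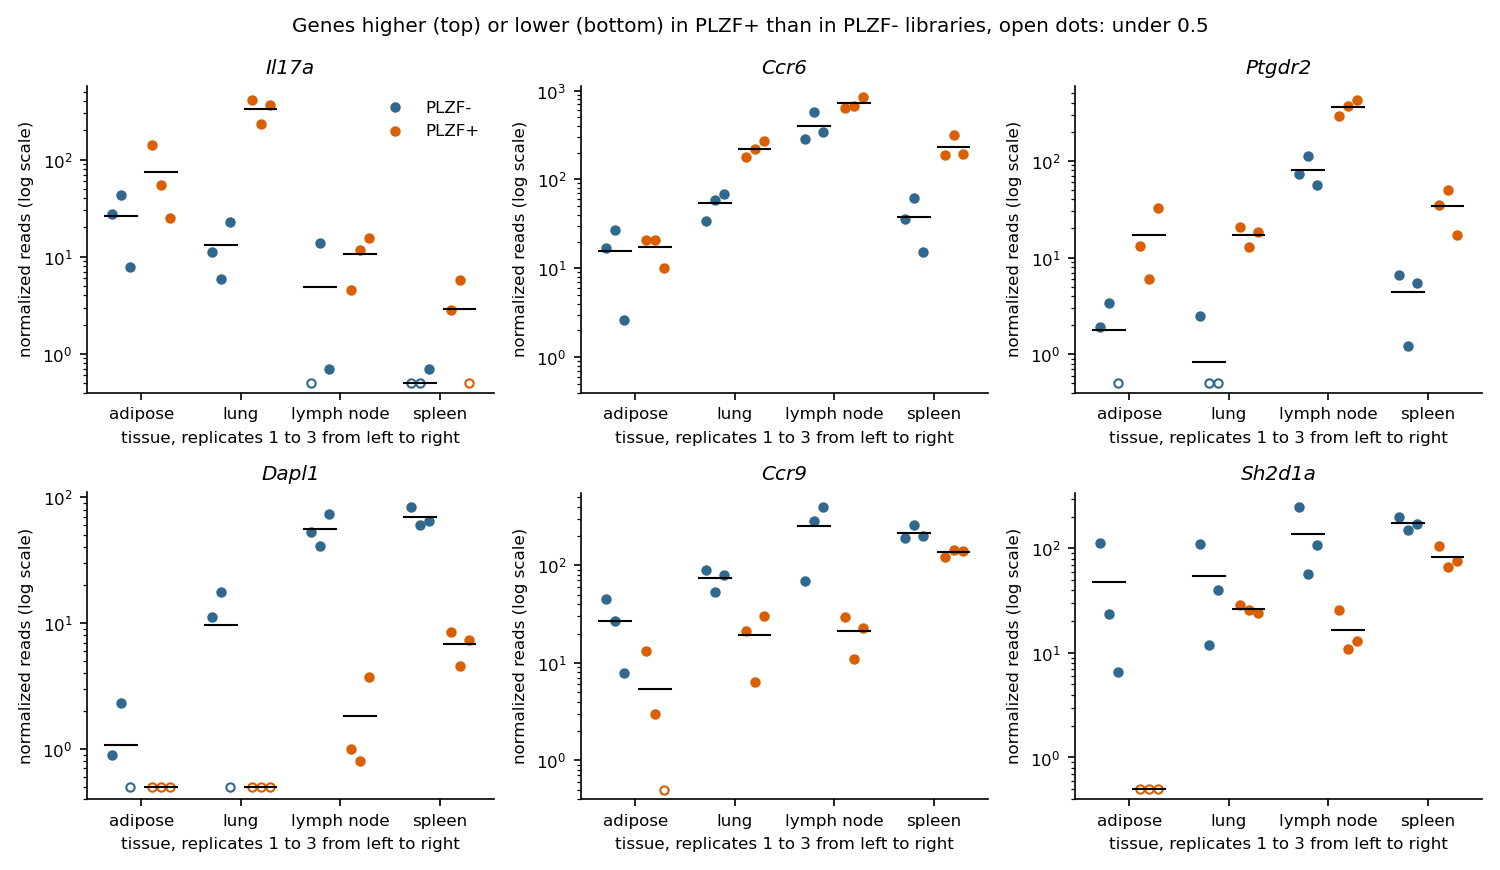
Normalized reads of Il17a, Ccr6 and Ptgdr2 (higher in PLZF+ cells) and of Dapl1, Ccr9 and Sh2d1a (lower) in each library, by tissue and subset, with bars at the mean of 3 libraries. Open dots mark libraries under 0.5 normalized reads.

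Within adipose tissue, PLZF+ cells had 0 reads of Sh2d1a in 3 libraries against 111.7, 23.7 and 6.6 normalized reads in PLZF- libraries 1 to 3 (-4.98 ± 0.75, adjusted p = 0.00888, n = 3 v 3). Sh2d1a was at least 8.88-fold lower, or 2.84-fold without PLZF- adipose 1, the library that carries this limit. Cd7, a membrane protein of T and NK cells (-3.90 ± 0.66, adjusted p = 0.0222; 6.21 ± 6.00 against 113 ± 106), and Slamf6, a SLAM-family receptor that signals through SAP (-1.93 ± 0.37, adjusted p = 0.0404; 8.55 ± 4.15 against 36.6 ± 17.4), were lower too. In all 1 gene was higher and 4 lower (recovered reads: 0 higher, 3 lower, all 3 shared). Naive and lymphoid homing genes leaned down, 1 of 5 fell and 0 rose (2 over the list alone), and γδ T cell receptor genes up, 0 of 11 past the test (6 over the list alone). Naive and T cell receptor genes had camera adjusted p = 4.71e-06 and 4.3e-06 (0.0958 and 0.195 estimated). Immediate early genes leaned down, 0 of 26 past the test (0 over the list alone). Camera gave these adjusted p = 0.000456 (0.129 to 0.260 without PLZF+ adipose 1 or PLZF- adipose 3, 0.488 estimated). The 3 IFN-gamma and cytotoxic genes and the 3 inhibitory receptors leaned down with 0 past the test in each (0 and 1 over each list alone). Camera gave these 2 lists adjusted p = 0.0319 and 0.0450 (0.442 and 0.295 estimated). Without PLZF+ adipose 2 or 3 or PLZF- adipose 1 the first passed no more (camera adjusted p = 0.0578 to 0.446). The second passed no more without PLZF+ adipose 1, 2 or 3, PLZF- adipose 1 or 2, PLZF- lung 1 or 2, PLZF- lymph node 3 or PLZF- spleen 1 (camera adjusted p = 0.0514 to 0.319). Equal replicate numbers pair the sorts in this tissue, and with a block within tissue 2 genes passed and Slamf6 did not (adjusted p = 0.0574). By limma voom 0 genes passed (140 at unadjusted p < 0.05). The count was 1 without PLZF+ adipose 3, 3 without PLZF- lymph node 3 or PLZF+ adipose 1, and 2 without any other library except PLZF- adipose 1, PLZF- adipose 3, PLZF- lung 1, PLZF+ lung 1 and PLZF+ lung 2. Cd7 was lost without PLZF- adipose 1, PLZF+ adipose 2 or PLZF+ adipose 3 (adjusted p = 0.0602 to 0.184), and Slamf6 without any library but PLZF+ adipose 1, PLZF- adipose 3 and PLZF+ lung 1 (adjusted p = 0.0522 to 0.283).

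In spleen, PLZF+ cells held more Dcc, a netrin receptor (4.63 ± 0.86, adjusted p = 0.0208; 11.7 ± 4.3 against 0.337 normalized reads, n = 3 v 3), and more Pld1, a phospholipase D (4.24 ± 0.85, adjusted p = 0.0439; 19.2 ± 2.7 against 2.07). On recovered reads of the same genes neither Dcc (adjusted p = 0.337) nor Pld1 (0.0874) passed, Dcc was too low for the recovered reads with their own filter, and Pld1 did not pass by voom (0.0514). Ccr6 did not pass (2.79 ± 0.63, adjusted p = 0.0739; 231.3 ± 72.5 against 37.5 ± 23.3), though it did on recovered reads (adjusted p = 0.0430). All 8 genes past the test were higher (recovered reads: 6 higher and 3 lower, 3 shared). The median over all genes was 0.49 as deposited, -0.07 on recovered reads and -0.21 after quantile scaling. That shift may favour higher calls and lists that lean down. Markers of other cells took 1.13%, 6.49% and 0.769% of reads in PLZF- and 3.58%, 4.36% and 3% in PLZF+ spleen libraries 1 to 3. Igkc, an immunoglobulin chain of B cells, stood at 91.1, 2001 and 18.8 normalized reads against 1296, 3301.5 and 1535. Naive and lymphoid homing genes leaned down with 0 of 5 past the test (3 over the list alone). Camera gave naive genes adjusted p = 1.29e-05 (0.0958 estimated). Markers of αβ T cells leaned down with them, 0 of 5 past the test (1 over the list alone), at 0.805% ± 0.113 of reads in PLZF- and 0.664% ± 0.043 in PLZF+ libraries. By camera αβ markers had adjusted p = 0.00310 (0.327 estimated). Fatty acid synthesis genes leaned down as well, 0 of 4 past the test (0 over the list alone). By camera they had adjusted p = 0.0185 (0.0537 without PLZF+ spleen 2, 0.266 estimated). Immediate early genes leaned down with 0 of 26 past the test (1 over the list alone, camera adjusted p = 4.34e-06, 0.320 estimated). On recovered reads camera gave naive and immediate early genes adjusted p = 0.0013 and 0.0043. There αβ markers and fatty acid synthesis genes did not pass (0.054 and 0.076). Dcc was lost without PLZF+ spleen 1, PLZF+ spleen 3, PLZF- spleen 1 or PLZF- spleen 3 (adjusted p = 0.0814 to 0.239), and Pld1 without any PLZF+ library of adipose tissue, lung or spleen, PLZF+ lymph node 3, PLZF- lung 2 and 3, PLZF- lymph node 2, or PLZF- spleen 1 and 3 (adjusted p = 0.0502 to 0.307). Ccr6 passed without PLZF- adipose 2, PLZF- adipose 3 or PLZF- spleen 2 (adjusted p = 0.0135 to 0.0466) and with a replicate block (adjusted p = 0.0376). The 8 genes became 61 without PLZF- spleen 2, the PLZF- spleen library with most of these markers, 19, 14 and 15 without PLZF- adipose 1, 2 and 3, 15 without PLZF+ spleen 2, 4 and 5 without PLZF- spleen 1 and 3, and 3 without PLZF+ spleen 3.

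In lung, PLZF+ cells held more Hk2 (2.71 ± 0.42, adjusted p = 0.0126; 75.3 ± 24.1 against 10.3 ± 7.8 normalized reads, n = 3 v 3) and more Commd5, a COMM-domain protein (2.81 ± 0.46, adjusted p = 0.0145; 21.8 ± 8.6 against 1.03). Commd5 had 0 reads in PLZF- lung 2 and 3, where 3 reads equal 17.7 and 17.0 normalized reads, and by voom it did not pass (adjusted p = 0.320), unlike Hk2 (0.0255). Il17a differed by 4.57 ± 1.09 without passing (adjusted p = 0.175), and passed on recovered reads (adjusted p = 0.0253). The 2 genes that passed were both higher (recovered reads: 17 higher and 1 lower, 2 shared). IL-17 programme genes leaned up with 0 of 6 past the test (2 over the list alone), as did tissue residency genes with 0 of 9 (3 over the list alone) and γδ T cell receptor genes with 0 of 11 (5 over the list alone). By camera IL-17, residency and T cell receptor genes had adjusted p = 3.97e-05, 2.54e-05 and 2.08e-07 (0.0958, 0.0958 and 0.137 estimated). Myeloid markers, transcripts of other cells, leaned up as well, 0 of 17 past the test (1 over the list alone), with 6.39% ± 1.04 of reads in PLZF+ and 5.64% ± 2.43 in PLZF- libraries. For myeloid markers camera gave adjusted p = 0.00673 (0.112 without PLZF+ lung 1, 0.318 on recovered reads, 0.717 estimated). Immediate early genes also leaned up, with 0 of 26 past the test (0 over the list alone) and 8.79% ± 1.18 of reads in PLZF+ against 5.39% ± 2.07 in PLZF- libraries. Camera gave these adjusted p = 0.000365 (0.0696 without PLZF- lung 3, 0.134 on recovered reads, 0.478 estimated). Lipid uptake and storage genes leaned up, 0 of 14 past the test (0 over the list alone), and naive and lymphoid homing genes down, 0 of 5 (2 over the list alone). By camera lipid genes had adjusted p = 0.000775 (0.0638 without PLZF+ lung 1, 0.0937 on recovered reads, 0.195 estimated). For naive genes camera gave adjusted p = 0.0134 (0.108 to 0.564 without PLZF+ lung 2 or PLZF- lung 1, 0.327 estimated). Oxidative phosphorylation genes had camera adjusted p = 0.0405 (0.758 estimated), up with 0 of 13 past the test (0 over the list alone). They passed no more without PLZF+ lung 1, PLZF- lung 2 or PLZF- lung 3 (camera adjusted p = 0.512 to 0.773). Commd5 was lost without lung 2 or 3 of either subset (adjusted p = 0.0564 to 0.164). Hk2 was lost without PLZF+ lung 3 or PLZF- lung 2 or 3 (0.0564 to 0.0909). The count was 46 without PLZF- lung 1, 4 without PLZF- adipose 3 or PLZF+ lung 1, 1 without PLZF+ lung 2, and 0 by limma without PLZF- lung 2, PLZF- lung 3 or PLZF+ lung 3 (468 at unadjusted p < 0.05 with all libraries, 15 past the test by voom).

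In lymph node 6 genes were higher and 10 lower in PLZF+ cells (recovered reads: 9 higher and 14 lower, 13 shared). Markers of other cells took 3.76%, 0.404% and 0.378% of reads in PLZF- and 1.68%, 0.209% and 0.229% in PLZF+ lymph node libraries 1 to 3. Lyz2, a lysozyme of myeloid cells, stood at 5048.9, 22.2 and 8.5 against 655.7, 22.7 and 46.7 normalized reads, so library 1 stands apart in both subsets. Higher were Ablim3 (5.51 ± 1.09, adjusted p = 0.0284; 36.9 ± 13.0 against 0.821 normalized reads, n = 3 v 3), Prickle1 (4.44 ± 0.85, adjusted p = 0.0245; 21.1 ± 6.5 against 1.41) and Fgl2, a fibrinogen-like protein of regulatory lymphocytes (2.56 ± 0.51, adjusted p = 0.0293; 399 ± 47 against 68.7 ± 18.3). By voom Ablim3 (adjusted p = 0.514) and Prickle1 (0.157) did not pass, and a fit on the 6 lymph node libraries alone called 0 genes by limma (475 at unadjusted p < 0.05, 35 past the test by voom on all libraries). Lower were Cd8b1 (-5.15 ± 0.92, adjusted p = 0.0122; 8.64 ± 9.45 against 232 ± 134), Dapl1 (-4.91 ± 0.79, adjusted p = 0.00521; 1.85 against 55.8 ± 16.3) and BE692007 (-4.64 ± 0.49, adjusted p = 2.23e-05; 8.24 against 245 ± 189). Of 5 naive and lymphoid homing genes 1 fell and 0 rose (3 over the list alone), and of 5 αβ T cell markers 1 fell and 0 rose (2 over the list alone). Naive genes and αβ markers had camera adjusted p = 4.7e-07 and 0.00144 (0.0958 and 0.294 estimated), and passed on recovered reads. Glycolysis genes leaned up, 0 of 5 past the test (1 over the list alone). By camera they had adjusted p = 0.00678 (0.131 estimated, 0.0737 to 0.115 without PLZF+ lymph node 1 or PLZF- lymph node 2). On recovered reads it was 0.0718, with a median over all genes of 0.02 against -0.38 as deposited. With a replicate block within tissue 43 genes passed. Ablim3 was lost without PLZF+ lymph node 2 or 3 or PLZF- lymph node 1 or 3 (adjusted p = 0.105 to 0.173). The same range held for Prickle1 without PLZF+ lymph node 2 or 3 or PLZF- lymph node 1 or 2. Fgl2 was lost without any of the 6 lymph node libraries (adjusted p = 0.0599 to 0.153), Cd8b1 without PLZF+ lymph node 2 or 3 or PLZF- lymph node 1 (adjusted p = 0.0800 to 0.153) and Dapl1 without PLZF+ lymph node 2 (adjusted p = 0.0698). The count of 16 became 9, 10 and 10 without PLZF- lymph node 1, 2 and 3, and 2 and 4 without PLZF+ lymph node 2 and 3.

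A test of whether the PLZF difference varies between the 4 tissues called 4 of 5858 genes (recovered reads: 2 of 2846, 1 shared; 405 at unadjusted p < 0.05, 1 past the test by voom). For nearly all genes a call in 1 tissue and none in another is therefore not shown to be a difference between tissues. Slamf6 was among the 4 (adjusted p = 0.0337): lower in PLZF+ cells of lymph node (-3.42), adipose tissue (-1.93) and lung (-1.05), but 0.26 in spleen (SE 0.37 each). P2rx7, an ATP-gated channel, did not pass (adjusted p = 0.115; 1.45 ± 0.52 in adipose tissue and -2.18 ± 0.52 in lymph node), nor did Commd5 (0.115), Acp5, an acid phosphatase (0.158), Epo, erythropoietin (0.158), Dcc (0.158) and Them6 (0.174). Commd5 passed without PLZF+ lung 1 (0.0476), Dcc and Epo without PLZF- lung 1 (0.0363 and 0.0459), and Acp5 and Them6 without PLZF- adipose 1 (0.0367 and 0.00638). P2rx7 passed without PLZF+ lymph node 1, PLZF- lung 1 or PLZF- lymph node 1 (0.0314 to 0.0363). The call of Slamf6 ended without any 1 of 9 libraries (0.0544 to 0.114). The count of 4 became 17 without PLZF- lung 1, 7 without PLZF- adipose 1 or PLZF+ lymph node 1, and 2 without PLZF+ adipose 3. It was 1 without PLZF- adipose 2, PLZF- lymph node 3, PLZF+ adipose 1 or PLZF+ lymph node 3, and 0 by limma without PLZF- lung 3, PLZF+ lymph node 2 or any 1 of the 6 spleen libraries.

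PLZF+ cells of adipose tissue were set against PLZF+ cells of spleen and lymph node (n = 3 v 6). They held more of the lipid droplet genes Hilpda (4.31 ± 0.41, adjusted p = 7.23e-07; 468 ± 207 against 22.5 ± 5.2 normalized reads) and Plin2 (3.35 ± 0.47, adjusted p = 6.03e-05) and more Dgat1 (3.94 ± 0.41, adjusted p = 2.57e-06; 673 ± 228 against 43.2 ± 11.1). Lower were Itgae (-4.82 ± 0.63, adjusted p = 2.5e-05; 17.4 ± 5.5 against 688 ± 507), Ccr10 (-6.33 ± 0.55, adjusted p = 2.87e-07), Cd7 (-5.81 ± 0.57, adjusted p = 1.2e-06), Cd6, a T cell co-receptor (-5.48), and Dtx1, a Notch pathway ligase read in 0 of 3 adipose libraries and at 156 ± 79 in the other 6 (-7.35 ± 0.68, adjusted p = 6.21e-07, at least 29.3-fold lower). Il17a was higher (3.82 ± 0.94, adjusted p = 0.00715; 74.1 ± 60.5 against 6.75) while Ccr6 was lower (-4.52 ± 0.54, adjusted p = 1.38e-05; 17.3 against 475 ± 279). Among the largest increases were genes known from other adipose cells: Cldn5, an endothelial tight junction protein (11.16 ± 1.71, adjusted p = 0.000151; 2725 ± 2636 against 0.297), Dcn, a fibroblast matrix protein (9.46 ± 1.73), Fabp4, a fatty acid carrier of fat and endothelium (9.06 ± 1.46), Cfd, an adipocyte protease (8.79), Aqp1 (8.73) and Sparcl1 (8.69), with Retnla, a macrophage product (9.66 ± 1.16, adjusted p = 1.38e-05; 1173 ± 921 against 1.51), and Thbs1, thrombospondin 1 (8.27 ± 0.69, adjusted p = 1.59e-07). In all 1483 genes were higher and 520 lower (recovered reads: 935 and 544, 1290 shared), with a median over all genes of 1.17 as deposited and 0.22 on recovered reads. After quantile scaling 533 were higher and 965 lower, and with the same median in each library 1052 and 697.

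Grouped by list in PLZF+ adipose cells, 10 of 14 lipid uptake and storage genes were higher, 1 lower and 3 not past the test (10 and 1 over the list alone), their median lying 2.16 above that of all genes. Like the endothelial markers, the lipid list took more reads in PLZF+ adipose libraries 2 and 3 (2.67% and 3.54%) than in library 1 (1.05%). By camera lipid genes had adjusted p = 0.00568 (0.295 estimated). All 5 naive and lymphoid homing genes were lower, among them Ccr9 (-3.69) and Tcf7, a transcription factor of naive T cells (-2.50 ± 0.55; 5 over the list alone). By camera naive genes had adjusted p = 2.49e-06 (0.0958 estimated). Of 9 type 2 and repair genes 6 were higher and 0 lower, such as Areg (4.72 ± 0.85, adjusted p = 0.000842), Calca (4.21), Penk (4.44) and Pparg, a regulator of lipid genes (4.05; 7 over the list alone). For type 2 genes camera gave adjusted p = 0.0346 (0.295 estimated). It was 0.0550 to 0.0961 without PLZF- lung 1, PLZF+ adipose 1 or PLZF+ lung 1. Of 6 IL-17 programme genes 3 were higher and 2 lower (3 and 2 over the list alone). Camera gave IL-17 genes adjusted p = 0.203 (0.594 estimated). Glycolysis was split, with Hk2 (2.50 ± 0.36, adjusted p = 7.61e-05; 80.7 ± 24.3 against 13.9 ± 2.4) and Hk3 (1.72) higher and Aldoc (-1.74, adjusted p = 0.0494) lower of 5 (2 and 1 over the list alone), and its median against all genes changed sign with the scaling (-0.21 as deposited, 0.72 on recovered reads). By camera glycolysis genes had adjusted p = 0.699 (0.955 estimated). Of 13 oxidative phosphorylation genes Cox7c was lower (-1.07 ± 0.37, adjusted p = 0.0352), 0 were higher and 12 not past the test (0 over the list alone), the median lying 1.76 below that of all genes, or 0.82 below on recovered reads. By camera oxidative phosphorylation genes had adjusted p = 0.00145 (0.571 estimated). γδ T cell receptor genes were lower, 6 of 11 (9 over the list alone), such as the segments Tcrg-V7 (-3.48) and Trgv2 (-1.85). For T cell receptor genes camera gave adjusted p = 1.86e-07 (0.137 estimated). All 26 immediate early genes were higher (26 over the list alone), Fosl2 foremost (5.48 ± 0.40, adjusted p = 4.46e-08; 1662 ± 252 against 38.9 ± 13.1). By camera immediate early genes had adjusted p = 5.41e-13 (0.112 estimated). Markers of other cells rose with them: 8 of 8 adipocyte, 13 of 14 fibroblast, 7 of 9 endothelial and 8 of 17 myeloid genes (8, 14, 9 and 9 over each list alone). Markers of αβ T cells were lower, 4 of 5 (4 over the list alone; camera adjusted p = 0.000169, 0.195 with an estimated correlation), and of 12 B cell markers 1 was higher and 3 lower (1 and 3 over the list alone; 0.00145 and 0.504). Camera gave the 4 lists of other adipose cells adjusted p = 0.00121, 0.0002, 0.0146 and 0.0137 (0.442, 0.519, 0.645 and 0.758 estimated). The myeloid list had camera adjusted p = 0.0980 without PLZF+ adipose 1. The count of 2003 genes became 854 without PLZF+ adipose 2, 593 without PLZF+ adipose 3 and 1328 without PLZF+ lymph node 3.

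PLZF- cells of adipose tissue were set against PLZF- cells of spleen and lymph node (n = 3 v 6). Plin2 (4.40 ± 0.47, adjusted p = 5.2e-06), Dgat1 (3.84 ± 0.41), Hilpda (3.17 ± 0.41) and Dgat2 (4.37 ± 0.66) were higher, and so were Areg (5.88 ± 0.85, adjusted p = 6.7e-05) and Il5, a cytokine for eosinophils (6.53 ± 0.93, adjusted p = 5.71e-05; 66.4 ± 88.1 normalized reads against 0 reads, at least 34.5-fold higher, or 8.34-fold without PLZF- adipose 1). Il5 fell over PLZF- adipose libraries 1 to 3 (167.1, 28.2 and 3.9 normalized reads). So did the 1 tested NK and innate lymphoid marker (142.2, 34.93 and 19.68) and CD3 genes (1090, 740.3 and 368.6). The source of Il5 and type 2 genes is thus open. Lower were Dtx1 (-5.60), Dapl1 (-5.57 ± 0.68, adjusted p = 1.2e-05), Cd8b1 (-5.26), Ccr10 (-4.93), Art2b (-4.64), Zfp296 (-4.37), Cand2 (-4.24) and Mgst2 (-4.14). Among the largest increases were Retnla (9.90 ± 1.16, adjusted p = 8.83e-06), Sparc (9.29), Sparcl1 (9.28), Cav1 (9.06), Fabp4 (9.20), Adamts1 (9.58), Cyr61 (9.32) and the chemokine Cxcl1 (9.24 ± 0.95, adjusted p = 2.83e-06; 401 ± 432 against 0 reads, at least 208.5-fold higher, or 86.1-fold without PLZF- adipose 3). In all 1516 genes were higher and 735 lower (recovered reads: 1196 and 740, 1735 shared), with a median over all genes of 0.55 as deposited, 0.54 on recovered reads and -0.33 after quantile scaling. After that scaling 804 were higher and 1142 lower. The count of 2251 became 1381 without PLZF- adipose 2 and 1035 without PLZF- adipose 3.

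Lists in PLZF- adipose cells: 10 of 14 lipid uptake and storage genes were higher and 1 lower (10 and 1 over the list alone), and 8 of 9 type 2 and repair genes were higher, Nfil3 (4.05 ± 0.60) among them, with 0 lower (8 over the list alone). The lipid list took 0.627% of reads in PLZF- adipose library 1 but 3.72% and 4.72% in libraries 2 and 3, where endothelial markers were high too. Lipid and type 2 genes had camera adjusted p = 0.00145 and 0.000526 (0.220 and 0.0958 estimated). All 5 naive and lymphoid homing genes were lower, Tcf7 by -3.98 ± 0.55 and Foxp1 by -1.62 ± 0.33 (5 over the list alone). Camera gave naive genes adjusted p = 4.71e-06 (0.0958 estimated). IL-17 programme genes went both ways, with Il17a (4.40 ± 0.94, adjusted p = 0.00173) and Stat3 (1.33 ± 0.31) higher and Ccr6 (-3.27 ± 0.54) and Batf (-1.66) lower of 6 (2 and 2 over the list alone). For IL-17 genes camera gave adjusted p = 0.597 (0.926 estimated). The median of these 6 changed sign with the scaling (0.10 as deposited, -0.45 after quantile scaling). Of 5 glycolysis genes Hk2 (2.16 ± 0.36) and Slc16a3 (1.80 ± 0.57) were higher and 0 lower (3 over the list alone). Camera gave glycolysis genes adjusted p = 0.266 (0.554 estimated). Of 13 oxidative phosphorylation genes 1 was lower, Cox7a2l (-1.09 ± 0.35, adjusted p = 0.0189), and 0 higher (0 over the list alone), with 5 lower on recovered reads. Camera gave oxidative phosphorylation genes adjusted p = 0.00158 (0.574 estimated). γδ T cell receptor genes were lower, 10 of 11, with Cd3d (-2.31 ± 0.36) and Cd3e (-2.10 ± 0.37) among them (11 over the list alone). By camera T cell receptor genes had adjusted p = 4.76e-10 (0.0958 estimated). Other cells dilute T cell RNA, so lower T cell genes in adipose tissue or lung, in either subset, may be dilution in part. Here Foxp1 fell less than Cd3d and Cd3e, and Tcf7 more. All 26 immediate early genes were higher, Fosl2 by 5.05 ± 0.40 (26 over the list alone). Camera gave immediate early genes adjusted p = 6.87e-13 (0.114 estimated). So were all 8 adipocyte, 14 fibroblast and 9 endothelial markers and 12 of 17 myeloid markers (8, 14, 9 and 15 over each list alone). All 5 αβ T cell markers were lower (5 over the list alone; camera adjusted p = 4.86e-06, 0.131 with an estimated correlation), and of 12 B cell markers 4 were lower and 1 higher (4 and 1 over the list alone; 0.0184 and 0.613, or 0.0775 without PLZF- spleen 2). By camera the 4 lists of other adipose cells had adjusted p = 0.000905, 0.000169, 0.00584 and 0.00158 (0.441, 0.519, 0.594 and 0.627 estimated).

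PLZF+ lung cells held more Il17a than PLZF+ cells of spleen and lymph node (6.27 ± 0.94, adjusted p = 0.000164; 334 ± 92 against 6.75 ± 5.82 normalized reads, n = 3 v 6), more Il17f, its close relative (4.71 ± 1.10, adjusted p = 0.00625), and more Areg (6.84 ± 0.85, adjusted p = 2.34e-05). Hk2 (2.41 ± 0.36, adjusted p = 0.000164) and Dgat1 (3.47 ± 0.41, adjusted p = 1.53e-05) were higher as well. Among the largest increases were Chil3, a chitinase-like macrophage protein (8.91 ± 1.22, adjusted p = 6.63e-05; 2567 ± 764 against 7.90), Cd14, the lipopolysaccharide co-receptor (8.29 ± 0.66, adjusted p = 1.18e-07; 528 ± 18 against 5.11), Plet1 (8.73), the keratins Krt19 (8.28) and Krt79 (7.76), Cxcl2 (7.88), Cldn5 (7.77) and Car4 (7.70). Lower were Trbv3, a variable segment of the T cell receptor β chain (-3.52 ± 0.47, adjusted p = 4.3e-05), Pydc3 (-3.65), RP23-423P21.1 (-3.55, at least 1.61-fold), Exo5 (-3.05), Mitd1 (-2.95), Lpar5 (-2.91) and Wbscr27 (-2.80). Without PLZF+ lung 2, Mitd1 (-1.54, adjusted p = 0.0658) and Lpar5 (-1.80, adjusted p = 0.112) passed no more. In all 1850 genes were higher and 363 lower, 83.6% higher; on recovered reads 672 and 317, 67.9% higher (926 shared), and after quantile scaling 394 and 825, 32.3% higher (1026 and 626 with the same median in each library). The median over all genes was 1.39 as deposited, 0.19 on recovered reads and -0.01 after quantile scaling. The count of 2213 became 3340, 590 and 818 without PLZF+ lung 1, 2 and 3.

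By list, 12 of 14 lipid uptake and storage genes were higher in PLZF+ lung cells and 0 lower, with Hilpda (2.96 ± 0.41), Dgat2 (4.56 ± 0.66) and Plin2 (3.02 ± 0.47; 14 over the list alone). For lipid genes camera gave adjusted p = 0.000129 (0.135 estimated). Of 5 glycolysis genes Hk2, Hk3 (2.59 ± 0.63) and Slc16a3 (1.80 ± 0.57) were higher and 0 lower (3 over the list alone). For glycolysis genes camera gave adjusted p = 0.176 (0.442 estimated). None of 13 oxidative phosphorylation genes passed (0 over the list alone), while their median lay 2.10 below that of all genes as deposited and 0.92 below on recovered reads. For oxidative phosphorylation genes camera gave adjusted p = 2.49e-06 (0.327 estimated). Of 6 IL-17 programme genes 2 were higher, Il17a and Il17f, and 0 lower (2 over the list alone). By camera IL-17 genes had adjusted p = 0.860 (0.955 estimated). Of 9 type 2 and repair genes 5 were higher, Nfil3 (2.79 ± 0.60) and Pparg (4.87 ± 1.08) among them, and 0 lower (6 over the list alone). Camera gave type 2 genes adjusted p = 0.111 (0.442 estimated). Cd7 (-2.19 ± 0.57) and Dapl1 (-2.10 ± 0.68) were the 2 of 5 naive and lymphoid homing genes that were lower, with 0 higher (2 over the list alone). For naive genes camera gave adjusted p = 0.00145 (0.195 estimated). γδ T cell receptor genes were lower, 6 of 11 (9 over the list alone), Cd3d by -1.17 ± 0.36. So was 1 of 5 αβ T cell markers (2 over the list alone, camera adjusted p = 0.00678, 0.395 estimated). Camera gave T cell receptor genes adjusted p = 9.93e-09 (0.114 estimated). Of 26 immediate early genes 22 were higher and 0 lower (22 over the list alone), beside 14 of 17 myeloid, 5 of 6 epithelial, 5 of 9 endothelial and 4 of 6 neutrophil markers (14, 5, 6 and 5 over each list alone). These 4 lists of other cells had camera adjusted p = 0.000607, 0.146, 0.1999 and 0.224 (0.594, 0.700, 0.925 and 0.824 estimated). Myeloid markers took 6.39% ± 1.04 of reads in PLZF+ lung, 1.62% ± 0.73 in PLZF+ spleen and 0.55% ± 0.84 in PLZF+ lymph node libraries. Lipid and type 2 genes may thus come from other lung cells in part, and their source is open. For immediate early genes camera gave adjusted p = 7e-10 (0.157 estimated).

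PLZF- lung cells held more Slc16a3 than PLZF- cells of spleen and lymph node (3.59 ± 0.57, adjusted p = 0.00023, n = 3 v 6), more Areg (6.16 ± 0.85, adjusted p = 0.000109) and more Il17a (3.73 ± 0.94, adjusted p = 0.00296). On recovered reads these were 3.49 ± 0.52, 4.57 ± 0.83 (27.1 ± 17.3 against 0.0687 normalized reads) and 2.66 ± 0.82 (13.2 ± 8.5 against 2.64), all past the test. CD3 genes were lower, Cd3g by -2.49 ± 0.39 (adjusted p = 0.000199) and Cd3d by -2.17 ± 0.36. Among the largest increases were Chil3 (7.91 ± 1.22, adjusted p = 0.000189), Olr1, a scavenger receptor (7.26), Cxcl2 (7.14), Sftpc, a surfactant protein of alveolar epithelium (7.01; 1.2, 588.6 and 62.2 normalized reads in libraries 1 to 3 against 0 reads, at least 112.9-fold higher, or 16.5-fold without PLZF- lung 2), Spp1 (6.97), Atf3 (6.94), Plet1 (6.83) and Lpl, lipoprotein lipase (6.69 ± 1.28, adjusted p = 0.000647). Lower were Ccr10 (-4.36 ± 0.55, adjusted p = 5.02e-05), Commd5 (-3.56 ± 0.40, adjusted p = 1.76e-05; 1.03 against 36.8 ± 10.1 normalized reads), Tbxa2r, the thromboxane receptor (-4.40), Sit1, a T cell adaptor (-3.85), Armc7 (-3.81), Fam26f (-3.65), Snhg20 (-3.55) and Alkbh4 (-3.45). In all 3601 genes were higher and 930 lower, 79.5% higher; on recovered reads 817 and 932, 46.7% higher (1701 shared), and after quantile scaling 674 and 1200, 36.0% higher. A library with few reads lifts its zeros in this table, and the median over all genes was 2.18 as deposited but 0.17 on recovered reads, so the count on recovered reads bears on this comparison more than the deposited one. The count of 4531 became 2603 and 2791 without PLZF- lung 2 and 3.

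Among the lists for PLZF- lung cells, 12 of 13 oxidative phosphorylation genes were lower and 0 higher, such as Cox7a2l (-1.44 ± 0.35, adjusted p = 0.00231), Ndufs4 (-1.38 ± 0.34, adjusted p = 0.00244) and Ndufb2 (-1.75 ± 0.48; 12 over the list alone), and 12 were lower on recovered reads too. Oxidative phosphorylation genes had camera adjusted p = 1.31e-07 (0.280 estimated), or 0.00234 (0.668 estimated) on recovered reads. Their median lay 3.41 below that of all genes as deposited and 1.52 below on recovered reads. The oxidative phosphorylation list took 0.342% of reads in PLZF- lung library 1 but 0.164% and 0.171% in the shallow libraries 2 and 3, where endothelial markers took 0.546% and 0.107% (0.0204% in library 1). Of 14 lipid uptake and storage genes 10 were higher and 0 lower, with Dgat1 (2.99 ± 0.41) and Plin2 (3.27 ± 0.47; 9 over the list alone), their median lying 0.14 above that of all genes as deposited and 2.10 above on recovered reads. By camera lipid genes had adjusted p = 0.173 (0.613 estimated). Of 5 glycolysis genes 3 were higher, Aldoc (2.74 ± 0.67) and Hk3 (2.49 ± 0.63) beside Slc16a3, and 0 lower (4 over the list alone). By camera glycolysis genes had adjusted p = 0.480 (0.717 estimated). Of 9 type 2 and repair genes 8 were higher and 0 lower, Nfil3 (3.45 ± 0.60) and Il5 (4.31 ± 0.93) among them (8 over the list alone), with 3 of 8 on recovered reads. For type 2 genes camera gave adjusted p = 0.138 (0.478 estimated). Of 6 IL-17 programme genes 1 was higher, Il17a, and 1 lower (1 and 1 over the list alone). Camera gave IL-17 genes adjusted p = 0.212 (0.594 estimated). Dapl1 (-2.81 ± 0.68), Tcf7 (-2.17 ± 0.55) and Cd7 (-2.25 ± 0.57) were the 3 of 5 naive and lymphoid homing genes that were lower, with 0 higher (3 over the list alone). By camera naive genes had adjusted p = 0.00055 (0.157 estimated). γδ T cell receptor genes were lower, 10 of 11 (10 over the list alone). So were all 5 αβ T cell markers (5 over the list alone, camera adjusted p = 8.29e-05, 0.184 estimated). For T cell receptor genes camera gave adjusted p = 4.47e-10 (0.0958 estimated). Of 26 immediate early genes 19 were higher and 0 lower (19 over the list alone), Fosl2 by 4.27 ± 0.40, beside 13 of 17 myeloid, 6 of 6 epithelial, 8 of 9 endothelial, 7 of 14 fibroblast and 5 of 6 neutrophil markers (13, 6, 8, 7 and 6 over each list alone). Camera on these 5 lists gave adjusted p = 0.134, 0.2497, 0.540, 0.557 and 0.497 (0.948, 0.8001, 0.955, 0.955 and 0.955 estimated). Myeloid markers took 5.64% ± 2.43 of reads in PLZF- lung, 1.21% ± 1.30 in PLZF- spleen and 1.17% ± 1.97 in PLZF- lymph node libraries. The source of the lipid and type 2 genes is open here too. By camera immediate early genes had adjusted p = 0.00971 (0.613 estimated, 0.206 without PLZF- lung 1). Their median lay 0.03 above that of all genes as deposited but 2.28 above on recovered reads.

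**Figure D3:**
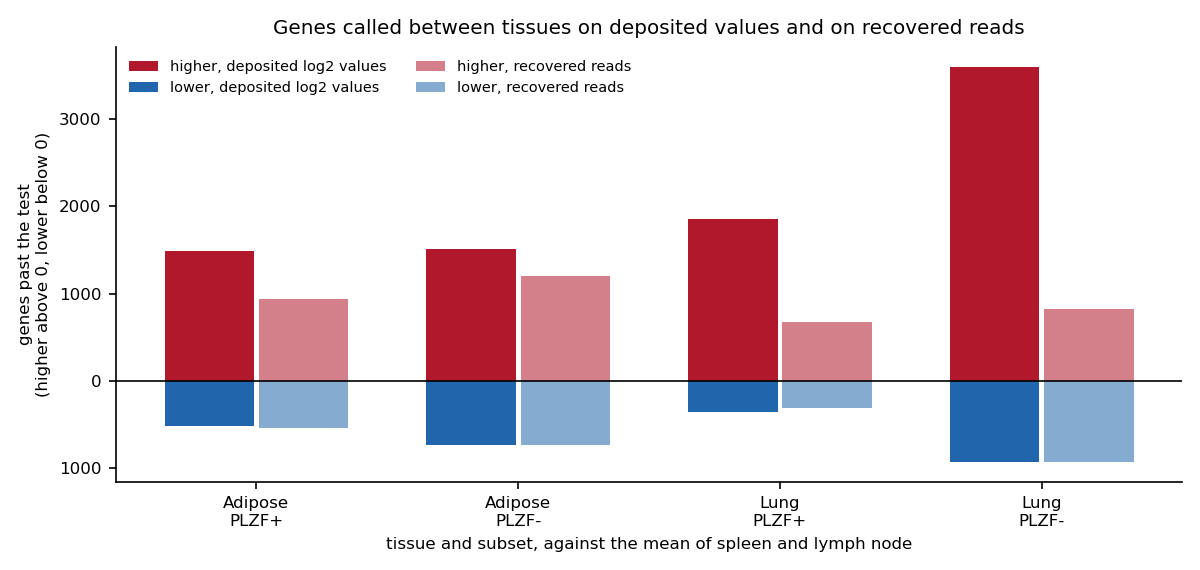
Genes higher (above 0) and lower (below 0) in adipose tissue or lung than in spleen and lymph node, for each subset, on the deposited log2 values and on recovered reads. Deposited values call more genes higher in lung, most of all in PLZF- cells, where 2 of 3 libraries are shallow.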

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

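The tests in this part with a limit set before the result was seen are those on zero reads, on adipose library 1 and on splits of the libraries, while the tests on lung cell markers, on immediate early genes and on the share of higher calls under other scales, filters and simulated reads and on splits that part pairs were chosen after the result was seen.

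For 4 genes the PLZF+ minus PLZF- difference varied between tissues by the interaction test. Slamf6, a SLAM-family receptor, had adjusted p = 0.0337, with 191 normalized reads in PLZF- and 18.4 in PLZF+ lymph node but 258 and 309 in spleen, and it held on recovered reads (adjusted p = 0.0240) and by voom (0.000297) but not on recovered reads with the genes of the deposited values (0.0569). BE692007 had adjusted p = 0.0484, with -4.64 in lymph node and -0.85, -0.92 and -1.13 in adipose tissue, spleen and lung (SE 0.49 each; recovered reads 0.0864, voom 0.252). Gm38359 (adjusted p = 0.0337; 4.50 ± 0.71 in spleen) and Gm13339 (adjusted p = 0.0339; 5.52 ± 0.69 in spleen, recovered reads 0.643, voom 0.252) are gene models named here after their values were seen. Leaving out any 1 of the 6 spleen libraries ended the calls of Slamf6, Gm38359, Gm13339 and BE692007. Other libraries that did so were PLZF+ lymph node 2, PLZF- lymph node 3 and PLZF- lung 3 for Slamf6 (9 of 24 in all, adjusted p = 0.0544 to 0.114), and PLZF+ adipose 1, PLZF+ lymph node 2 and 3, PLZF- adipose 2 and PLZF- lung 3 for Gm38359 (11, 0.0518 to 0.162). For Gm13339 they were PLZF+ adipose 1 and 3, PLZF+ lymph node 2 and 3, PLZF- adipose 2, PLZF- lung 3 and PLZF- lymph node 1 and 3 (14, 0.0527 to 0.157), and for BE692007 any but PLZF+ adipose 2, PLZF+ lymph node 1, PLZF- adipose 1, PLZF- lung 1, PLZF- lung 2 and PLZF- lymph node 1 (18, 0.0527 to 0.291). In 15 of 100 splits of the libraries at random at least 4 genes were called (highest other 61), so chance cannot be excluded for the interaction count. These splits ignore the pairs of equal number; with splits that part every pair in adipose tissue, lung and lymph node, 6 of 100 did so (highest other 32), which leaves it open too.

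The excess of higher calls in PLZF- lung was held against 2 technical explanations. A floor of zero reads that rises in shallow libraries predicted that over 50% of the genes called higher have 0 reads in both lung libraries 2 and 3; the value was 55.43% (1996 of 3601), which fits, against 17.2% of the 2255 genes tested and not called higher. On the same genes recovered reads called 957 higher and 916 lower (51.1% higher against 79.5%). Deposited values with the recovered reads' filter called 904 and 874 (50.8%), so the excess lies in genes with few reads on the deposited scale. Simulated reads without tissue change gave 1651 higher and 34 lower, on genes not picked by a tissue test, so not comparable with 3601. Whether the floor gives all of the excess is open. RNA of other lung cells predicted that over 50% of epithelial, myeloid, endothelial and fibroblast markers are higher on recovered reads; the value was 64.29% (27 of 42), but no excess is left on that scale, so this says nothing about it. RNA of other cells and a lung state of PLZF- cells stay open for the 817 genes higher on recovered reads, since none of the 24 libraries holds other lung cells alone.

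Genes higher in adipose cells could come from other adipose cells in libraries 2 and 3, where endothelial markers were high. If so, over 50% of genes called higher on recovered reads should have under 0.25 times the reads in library 1; the values were 41.07% in PLZF+ (384 of 935, median ratio 0.386) and 45.48% in PLZF- cells (544 of 1196, median ratio 0.312), between the limits of 10% and 50%, so the test cannot tell. The rest may reflect adipose residence of the T cells, which the design does not vary apart from the tissue itself.

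Immediate early genes were higher in adipose tissue and lung in both subsets, taking 8.13% ± 1.42 and 8.79% ± 1.18 of reads in PLZF+ adipose and lung libraries and 0.918% ± 0.149 in PLZF+ lymph node. If other cells of adipose libraries 2 and 3 brought them, the median difference in library 1 should be under 0.5 times that in libraries 2 and 3; it was 0.6217 times (2.79 against 4.48 over 25 genes), which cannot tell, while endothelial markers went from 0.77 to 6.93. Tissue digestion and activation in the tissue could both give this pattern, and no library tests them apart.

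Splits of the libraries at random were counted, the real one included. For PLZF averaged over tissues 2 of 100 splits reached the real 69 genes, which excludes chance at 5%, but the highest other split gave 235, so structure among the libraries that the groups do not capture can call more genes than PLZF does. With splits that part every pair in adipose tissue, lung and lymph node, 1 of 100 reached 69 and the highest other gave 3. The 8 lists were reached in 19 of 100 splits (highest other 12). In single tissues only 10 splits exist, too few: 2 in adipose tissue (real 5, highest other 9), 1 in spleen (8, 0), 5 in lung (2, 1012) and 2 in lymph node (16, 16). Of the 4 splits that part all 3 pairs of equal replicate number none but the real one called a gene in any tissue by limma, and the 9, 1012 and 16 come from splits that keep a pair together. The lung split with 1012 genes sets PLZF- lung 1 and PLZF+ lung 1 and 3 against the rest, which points to sample structure. Between tissues the genes of the table had been kept by a tissue test on these same libraries, so splits say nothing about chance there: 1 of 100 reached the real count in PLZF+ adipose (2003, highest other 33), PLZF- adipose (2251, 1119), PLZF+ lung (2213, 349) and PLZF- lung (4531, 2973). For lists, on the same genes, these were 14 of 100 splits in PLZF+ adipose (real 12, highest other 13), 10 in PLZF- adipose (14, 18), 35 in PLZF+ lung (7, 9) and 64 in PLZF- lung (5, 12).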

How the results depend on the processing

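Under the settings chosen before the data were examined, named genes kept direction and side of the threshold in 1207 cases, lost the call in 52 and gained it in 13; with 1 library left out these were 2836, 177 and 11. None reversed. Lists kept their call in 108 cases and lost it in 84 (63 with an estimated correlation, 20 by fry and 1 with a replicate block), and with 1 library left out these were 1484 and 51. In each setting where a count moved, the cause was not tested unless the setting itself shows it.

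Counts of genes past the test are given below beside the count as designed: PLZF averaged 69, adipose 5, spleen 8, lung 2, lymph node 16, PLZF+ adipose 2003, PLZF- adipose 2251, PLZF+ lung 2213, PLZF- lung 4531 and interaction 4. Quantile normalization gave 36 averaged, 1 in adipose, 2 in spleen, 5 in lymph node, 1219 for PLZF+ lung, 1874 for PLZF- lung and 0 for the interaction (362 at unadjusted p < 0.05). The same median in each library gave 3 in adipose and 1 in lung. Pseudocount 0.5 gave 2 in adipose, and pseudocount 5 gave 2 in adipose and 22 in lung. A filter of at least 5 gave 3 in adipose, 1440 for PLZF+ lung and 2753 for PLZF- lung, and no filter gave 3361 for PLZF+ lung. Library weights (arrayWeights) gave 198 averaged, 33 in adipose, 780 in spleen, 74 in lung, 161 in lymph node, 4229 for PLZF+ adipose, 3739 for PLZF- adipose, 4343 for PLZF+ lung and 404 for the interaction. With only the groups of the comparison, limma called 0 in adipose, 0 in lung and 0 in lymph node (124, 149 and 475 at unadjusted p < 0.05), 44 in spleen and 3693 for PLZF+ adipose. A replicate block gave 2 in adipose and 27 in spleen; a block within tissue gave 112 averaged, 2 in adipose, 14 in spleen and 43 in lymph node, with Pld1 in spleen at adjusted p = 0.0523. The pairing changed no other call than those given here and in the report.

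Recovered reads gave 3 in adipose, 18 in lung, 989 for PLZF+ lung, 1749 for PLZF- lung and 2 for the interaction; with pseudocount 5 they gave 1 in adipose, 9 in lung, 1053 for PLZF+ lung, 1734 for PLZF- lung and 2 for the interaction. Recovered reads with a block within tissue gave 197 averaged, 15 in adipose, 31 in spleen, 67 in lung and 66 in lymph node. With the scale alone changed, recovered reads on the genes of the deposited values, limma gave 75 averaged, 6 in adipose, 1 in spleen, 24 in lung, 927 for PLZF+ lung, 1873 for PLZF- lung and 0 for the interaction (288 at unadjusted p < 0.05). There Ifit1bl1 averaged (adjusted p = 0.0659), Dcc and Pld1 in spleen (0.337 and 0.0874) and Slamf6, BE692007, Gm38359 and Gm13339 in the interaction (0.0569, 0.0961, 0.806 and 0.593) lost the call, and Il17a in lung gained it (0.0281). With the filter alone changed, deposited values on the genes of the recovered reads, there were 25 in lymph node, 1022 for PLZF+ lung, 1778 for PLZF- lung and 5 for the interaction, where Commd5 and Acp5 gained the call (0.0424 and 0.0470). Voom gave 122 averaged, 0 in adipose (140 at unadjusted p < 0.05), 46 in spleen, 15 in lung, 35 in lymph node, 1063 for PLZF+ adipose, 773 for PLZF+ lung, 781 for PLZF- lung and 1 for the interaction. Voom lost Cldn5, Cfd, Aqp1 and Sparcl1 in PLZF+ adipose, Cyr61 and Sparcl1 in PLZF- adipose, Cldn5, Car4 and Lpar5 in PLZF+ lung, and Sftpc, Fam26f and Snhg20 in PLZF- lung. It also lost Ablim3 averaged and Sh2d1a, Cd7 and Slamf6 in adipose (adjusted p = 0.673, 0.677 and 0.639). Lost too were Pld1 in spleen, Commd5 in lung, Ablim3 and Prickle1 in lymph node and, in the interaction, BE692007 and Gm13339. These fits, and those without libraries 2 and 3, were chosen after the values were seen.

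Without adipose libraries 2 and 3, where the lone adipose library of a subset is assumed to vary like the other groups, deposited values gave 1 in adipose, 24 in spleen, 4 in lung, 27 in lymph node, 153 for PLZF+ adipose, 177 for PLZF- adipose and 1 for the interaction, and recovered reads 1, 22 in lung, 32 in lymph node, 187 for PLZF+ adipose, 207 for PLZF- adipose, 1160 for PLZF+ lung, 1893 for PLZF- lung and 1 for the interaction. Without lung libraries 2 and 3, limma on deposited values gave 41 averaged, 22 in spleen, 0 in lung (709 at unadjusted p < 0.05), 3310 for PLZF+ adipose, 147 for PLZF+ lung, 214 for PLZF- lung and 0 for the interaction (697), and on recovered reads 2 in adipose, 0 in lung (114), 27 in lymph node, 225 for PLZF+ lung, 84 for PLZF- lung and 0 for the interaction (130). Without adipose libraries 2 and 3, Dcn, Cfd, Aqp1 and Sparcl1 in PLZF+ and Adamts1, Cyr61, Sparc, Sparcl1, Fabp4, Cav1, Zfp296 and Mgst2 in PLZF- adipose lost the call. Recovered reads without both gave 261 averaged, 13 in adipose, 83 in spleen, 5 in lung, 85 in lymph node, 464, 435, 376 and 235 for PLZF+ adipose, PLZF- adipose, PLZF+ lung and PLZF- lung, and 2 for the interaction.

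With 1 library left out, counts ranged from 38 (PLZF+ spleen 2) to 75 (PLZF- adipose 3) averaged, 1 (PLZF+ adipose 3) to 6 (PLZF+ lung 1) in adipose, 3 (PLZF+ spleen 3) to 61 (PLZF- spleen 2) in spleen, 0 (PLZF- lung 2) to 46 (PLZF- lung 1) in lung, 2 (PLZF+ lymph node 2) to 24 (PLZF- adipose 1) in lymph node, 593 (PLZF+ adipose 3) to 2728 (PLZF- lung 1) for PLZF+ adipose, 1035 (PLZF- adipose 3) to 2752 (PLZF- adipose 1) for PLZF- adipose, 590 (PLZF+ lung 2) to 3340 (PLZF+ lung 1) for PLZF+ lung, 2603 (PLZF- lung 2) to 4689 (PLZF- adipose 1) for PLZF- lung and 0 (PLZF- lung 3) to 17 (PLZF- lung 1) for the interaction. Of 216 list tests 64 passed by camera, 1 with an estimated correlation, 71 by fry, 63 with a replicate block and 51 on recovered reads. The oxidative phosphorylation list in lung (PLZF+ against PLZF-, camera adjusted p = 0.0405) reversed direction without PLZF+ lung 1 (adjusted p = 0.773) and had 0.000265 without PLZF- lung 1. The test for whole counts named beforehand was not run, because the table holds log2 values; voom took its place. With an absolute log2 fold of at least 1 required as well, every call of a named gene stayed, with counts of 56 averaged, 1933 for PLZF+ adipose, 2163 for PLZF- adipose, 2155 for PLZF+ lung and 4367 for PLZF- lung and no change in single tissues.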

Other observations

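One test in this part, on CD3 genes, was chosen after the result was seen. Inhibitory receptors differed between tissues, but not all in the same direction: Ctla4, a brake on T cell activation, was higher in PLZF+ adipose cells than in spleen and lymph node (4.87 ± 1.02, adjusted p = 0.00234) and in PLZF+ lung cells (5.50 ± 1.02, adjusted p = 0.00123), and so was Entpd1, an ATP-degrading enzyme, in PLZF- adipose (4.48 ± 0.87) and PLZF- lung cells (4.14 ± 0.87). Cd160 was lower in each, -3.08 ± 0.57 in PLZF+ adipose and -2.64 ± 0.57 in PLZF+ lung cells, and lower in PLZF+ than in PLZF- cells over all tissues (-1.64 ± 0.33, adjusted p = 0.0132). In each of the 4 tissue comparisons this list of 3 counts 2 higher and 1 lower (camera adjusted p = 0.860 and 0.804 for PLZF+ and PLZF- adipose, 0.880 and 0.804 for PLZF+ and PLZF- lung). Ccl3 and Ccl4, chemokines of activated lymphocytes and of macrophages, and Cx3cr1, the fractalkine receptor, were all higher in PLZF+ lung (4.58 ± 1.12, 4.20 ± 1.17 and 2.66 ± 0.82) and PLZF- lung cells (4.01, 3.90 and 3.31), 3 of 3 genes of the IFN-gamma and cytotoxic list (camera adjusted p = 0.211 and 0.460, adjusted p = 0.669 and 0.895 with an estimated correlation). Myeloid cells make these too, and 14 of 17 myeloid markers were higher in PLZF+ and 13 of 17 in PLZF- lung (6.39% and 5.64% of reads), so the source of the 3 is open.

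Growth and transport genes were higher in adipose cells, 3 of 3 in each subset: Slc3a2, a partner of amino acid transporters (2.06 ± 0.29 in PLZF+, 1.45 ± 0.29 in PLZF-), Odc1, the first enzyme of polyamine synthesis (2.24 ± 0.76 and 3.39 ± 0.76), and Rheb, an activator of mTOR (1.22 ± 0.34 and 1.46 ± 0.34; camera adjusted p = 0.0978 and 0.0710). Fatty acid oxidation genes leaned the same way in adipose tissue, with 3 of 6 higher in PLZF+ and 4 of 6 in PLZF- cells and 0 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.300 and 0.0756), such as Cpt1a in PLZF- cells, which admits fatty acids to mitochondria (1.05 ± 0.31). This list took 0.114%, 0.137% and 0.162% of reads in PLZF+ and 0.115%, 0.199% and 0.187% in PLZF- adipose libraries 1 to 3, beside endothelial markers at 0.0632%, 1.38% and 1.85% and at 0.0150%, 1.80% and 2.19%. In lung Cpt1a was higher in both subsets (1.12 ± 0.31 and 1.07 ± 0.31), though the median of the list against all genes changed sign with the scaling (-0.93 as deposited and 1.03 on recovered reads in PLZF- lung). Tissue residency genes split: Rgs1 (2.34 ± 0.39) and Bhlhe40 (3.85 ± 0.64) were higher in PLZF+ lung cells and Ccr10 lower (-2.47 ± 0.55).

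The subsets, which share no libraries, overlapped in their tissue calls. On recovered reads 879 genes were higher and 399 lower in adipose tissue in both subsets, and 520 and 231 in lung. The genes of the table were kept by a tissue test that pooled the subsets, and equal numbers were taken to pair the sorts in adipose tissue and lung, so no count by chance is set beside these. Both sorts of a tissue meet the same other cells, so this overlap does not tell T cell genes from those.

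A hypothesis on CD3 genes was tested. They were higher in PLZF+ than in PLZF- libraries of adipose tissue (median log2 1.49) and lung (1.37), which a larger share of other cells in the PLZF- sorts could give. In that case the difference should vanish (under 0.25) in spleen and lymph node, and if it belongs to PLZF+ cells it should stay over 0.5; the median there was 0.3714 (0.28 in spleen, 0.46 in lymph node), so the test cannot tell. Markers of other cells did not take a clearly larger share in PLZF- sorts of lung or adipose tissue (shares above).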
